A study of Homo sapiens with 92 samples.

How the data were processed

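Polyadenylated RNA was sequenced from HEK293T cells, a line derived from human embryonic kidney, after lentiviral delivery of a short hairpin RNA (shRNA) and selection with puromycin. The growth notes write HEK293XT for these cells. The series holds 92 libraries, 2 for each of 40 knocked-down RNA-binding or RNA-related proteins. Each series group, A and B, has 6 libraries with a non-targeting hairpin. Per the labels a series group is the set of controls with which its knockdowns are compared. The labels do not say whether replicates are separate cultures, so every p-value below measures the spread between libraries labelled as replicates. Libraries were made with a stranded mRNA kit.

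The deposited files are transcript tables from Salmon, one per library, with the genome build hg38. The versions of Salmon, FastQC and the transcript annotation are not given in the sources used here. Per the file headers the authors deposited 3 kinds of value: expected counts (the number of reads that Salmon assigned to each transcript, not whole numbers), TPM (transcript abundance corrected for length and scaled to the same total over all listed transcripts) and an effective length in nucleotides for each transcript. All files list the same 108319 transcripts, 96 ERCC spike-ins and 1 phiX sequence. Expected counts per library had a median of 3331507 in group A and 3401506 in group B. Intervals and floors given for low counts cover counting error only, since reads without molecular identifiers are not independent molecules.

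Transcripts were assigned to genes through GENCODE release 29 by their identifier. This matched 88.7% of the transcripts, which hold 91.9% of the reads; 69.1% of the transcripts, with 46.8% of the reads, also matched in their version. A further 12257 transcripts, with 7.8% of the reads, matched no gene and were left out, as were spike-ins and phiX (0.25% of the reads). A gene can therefore lack part of its reads. For each gene the share of reads on unmatched transcripts listed within or beside its own was computed. Genes with any such reads, or with exons overlapping another gene on the same strand, are called uncertain below.

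Expected counts were summed per gene, rounded and tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1): filterByExpr, TMM normalisation and the robust quasi-likelihood test, with 1 fit per series group over all of its libraries. This left 13914 genes in group A and 13681 in group B, with 30 and 20 residual degrees of freedom. Each knockdown was tested against the 6 controls of its own group, two-sided, with Benjamini-Hochberg adjustment over the genes of that comparison and a threshold of 0.05. Genes past it are called higher or lower. Changes are log2 fold changes with a standard error (SE), taken as the absolute change over the square root of the F statistic; levels are CPM (counts scaled by the TMM-adjusted total of the library) with the SD of the 6 controls. When a library was left out, the remaining one of the knockdown was assumed to vary like the other groups. Where all libraries of a group had 0 reads, the fold is a lower bound against a floor of 3 reads over the group; with 1 to 3 reads it is a ratio with a 95% interval.

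A shift between 3′ ends was measured from TPM. Among transcripts of a gene that share the start of the last exon, those reaching the furthest end (distal) were set against those ending over 200 nt earlier (proximal). The log2 ratio of distal to proximal TPM, with a pseudocount of 0.5 TPM, was tested with limma (trend, robust) in genes with a mean of at least 5 TPM for both ends together and at least 0.5 TPM for each. Transcripts matched with their version entered, giving 1754 genes in group A and 1753 in group B. A negative shift is toward the proximal end. Where an end is near 0 TPM, the pseudocount sets the size of the shift. TPM estimates from reads over whole transcripts are not counts of cleaved ends.

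Gene lists were tested with camera, which compares the members of a list with all other genes, at a preset correlation of 0.01 and also with an estimated correlation; 895 tests of 23 lists were adjusted together. The lists hold cleavage and polyadenylation factors, 6 genes reported to change their 3′ end with cleavage factor Im (CFIm), replication-dependent histones, p53 targets, ATF4 targets, unfolded protein response chaperones, interferon-stimulated genes, cholesterol genes, cytosolic ribosomal proteins, targets and factors of nonsense-mediated decay, SR proteins with TRA2, hnRNP proteins, CCR4-NOT and mRNA decay factors, spliceosome snRNP proteins, selenoproteins, mitochondrially encoded genes, G2 and mitosis genes, S phase genes, heat shock genes, immediate early genes, hypoxia and glycolysis genes, and markers of haematopoietic cells and of fibroblasts as other cell types. Pairs of knockdowns were compared by correlation across genes. Because both share controls, the value was set against 20 simulated data sets with no change and against fits in which each knockdown had its own 3 controls.

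The comparisons, lists, pairs, tests and thresholds and the rule for named genes were fixed before the data were examined. By that rule the main comparisons are NUDT21, CPSF6 and the 6 other knockdowns with the most genes called. In each the text may name the target, its paralogs, the 10 largest rises and the 10 largest falls among called genes with an average log2 CPM of at least 2 and both libraries beyond all 6 controls, up to 4 members per list, and the 3 largest 3′ shifts each way. In the other 32 knockdowns the rule takes 2 rises and 2 falls. Many genes of that rule proved uncertain, so 8 rises and 8 falls among fully matched genes (no unmatched transcript, no overlap, log2 CPM of at least 3) were added after the values had been seen.

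The alternatives fixed with them were RLE factors, DESeq2 1.42.0, no filter on low counts, a fit with only the 8 libraries of a comparison, the replicate number as a block, offsets for transcript length, leaving out each library, and other settings of the 3′ measure. A correction for GC content per library (a spline with 4 degrees of freedom), the mean of the other knockdowns as reference, shares of all bases in the scan described next, own controls for the 3′ shifts of NUDT21 and CPSF6, and transcripts whose version differs were added after seeing the data. A scan of 3′ UTRs for words of 7 nt (7-mers) that mark lowered genes was also added then, and run with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3; figures were drawn with matplotlib 3.10.9. In simulated data with planted changes, edgeR called 26.9%, 61.2% and 84.8% of genes changed 1.5-, 2- and 4-fold in the NUDT21 comparison and 12 of 13074 unchanged genes. In the TRNAU1AP comparison these were 29.9%, 58.2% and 78.8%, with 2 of 12957. The 3′ test recovered 2% of planted shifts of 1 log2 unit in both groups, and 23% (group A) and 22% (group B) of shifts of 2. Results for 5 genes are not reported here.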

Results

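Of the 40 knockdowns, group A holds 25, with 6 controls (56 libraries), and group B 15, with 6 (36). By its title the series belongs to a screen for proteins that act on the choice of poly(A) site, the place at which an mRNA is cleaved and receives its tail. Expected counts summed to 2407829 to 5319841 reads per library in group A and to 1825808 to 9741903 in group B. Reads fell on 13747 to 15662 genes per library, and mitochondrially encoded genes took 4.14% to 10.5% of the reads. Against the mean of the controls, the changes of the 2 replicates of a knockdown correlated across genes with r from 0.395 (CPSF6) to 0.872 (TRNAU1AP). Genes are not independent replicates, and both replicates share their controls. Below, ± after a log2 change is its SE (n = 2 knockdown and 6 control libraries), and ± after a CPM is the SD of the 6 controls.

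The first question was how far each hairpin lowered its own target. NUDT21, the smaller subunit of cleavage factor Im (CFIm), which binds upstream of poly(A) sites, fell from 128 ± 11.9 CPM to 4.63 and 7.36 CPM, a log2 change of −4.45 ± 0.16 (adjusted p = 1.4e-23). CPSF6, the larger subunit of CFIm, fell from 305 ± 14.8 to 103 and 122 CPM (−1.44 ± 0.14, adjusted p = 3.4e-10). PPIA, a prolyl isomerase, fell by 4.76 ± 0.15 from 980 ± 87.2 CPM. RPS19BP1 fell by 3.54 ± 0.35, HNRNPF by 2.14 ± 0.11, TPD52L2 by 1.99 ± 0.16, MBNL2 by 1.91 ± 0.43 and TRNAU1AP by 1.06 ± 0.20. RBM42 fell by 3.97 ± 0.45, from 20.8 ± 3.63 CPM to 2.03 and 0 CPM. In all, 34 of the 40 targets passed the test, each of them lower. The labels state a knockdown above 50% for all sequenced samples, which may have been measured otherwise than by these read counts. Here the mean level of 32 targets was under 50% of the controls. ZC3HAV1 (52.5% of the controls), SMNDC1 (67.7%) and CNOT2 (72.3%) passed the test above that level, and with offsets for length their adjusted p were 0.916, 0.759 and 0.0840. For CNOT2 the change was −0.48 ± 0.14, or −0.24 (adjusted p = 0.345) without replicate 1 and −0.74 without replicate 2. PARN, a poly(A) ribonuclease, had 0 and 3 reads against 372 in the controls, a ratio of 45.5 (95% counting interval 15.6 to 221), with 51.8% of its reads on unmatched transcripts. Its call was lost without replicate 1 (adjusted p = 0.221) and without replicate 2 (adjusted p = 0.113), and RBM11 (−1.53 ± 0.30) lost it without replicate 2 (−1.12, adjusted p = 0.0747).

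The targets of 6 knockdowns did not pass the test. PCBP3 had 2 reads in each library against 63 in the controls (−2.28 ± 1.31, adjusted p = 0.194), and LGALS3 had 5 and 4 reads against 60 (−0.89 ± 0.64, adjusted p = 0.306). RBM14 stood at −0.66 ± 0.27 (adjusted p = 0.0770) and SCAF8 at −0.28 ± 0.12 (adjusted p = 0.0874). MBNL1 was at 47.8 and 45.5 CPM against 52.7 ± 6.18 in the libraries labelled MBNL1 (adjusted p = 0.412). DZIP3 was at 49.9 and 68.1 CPM against 59.3 ± 6.72 in the libraries labelled DZIP3, with a log2 change of 0.00 ± 0.17. Both MBNL1 levels lay within the range of the controls (43.8 to 61.8 CPM). For DZIP3 replicate 2 did, while replicate 1 lay below the lowest control (range 52.1 to 70.2 CPM). Of the other targets, the lowest was RBM14 (−0.97, adjusted p = 0.0123) in the libraries labelled DZIP3 and LSM10 (−1.43, adjusted p = 0.00222) in those labelled MBNL1. Unmatched transcripts held over 10% of the reads of 9 targets, PARN (51.8%), TRNAU1AP (42.5%) and NUDT21 (40.3%) the most.

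**Figure D1:**
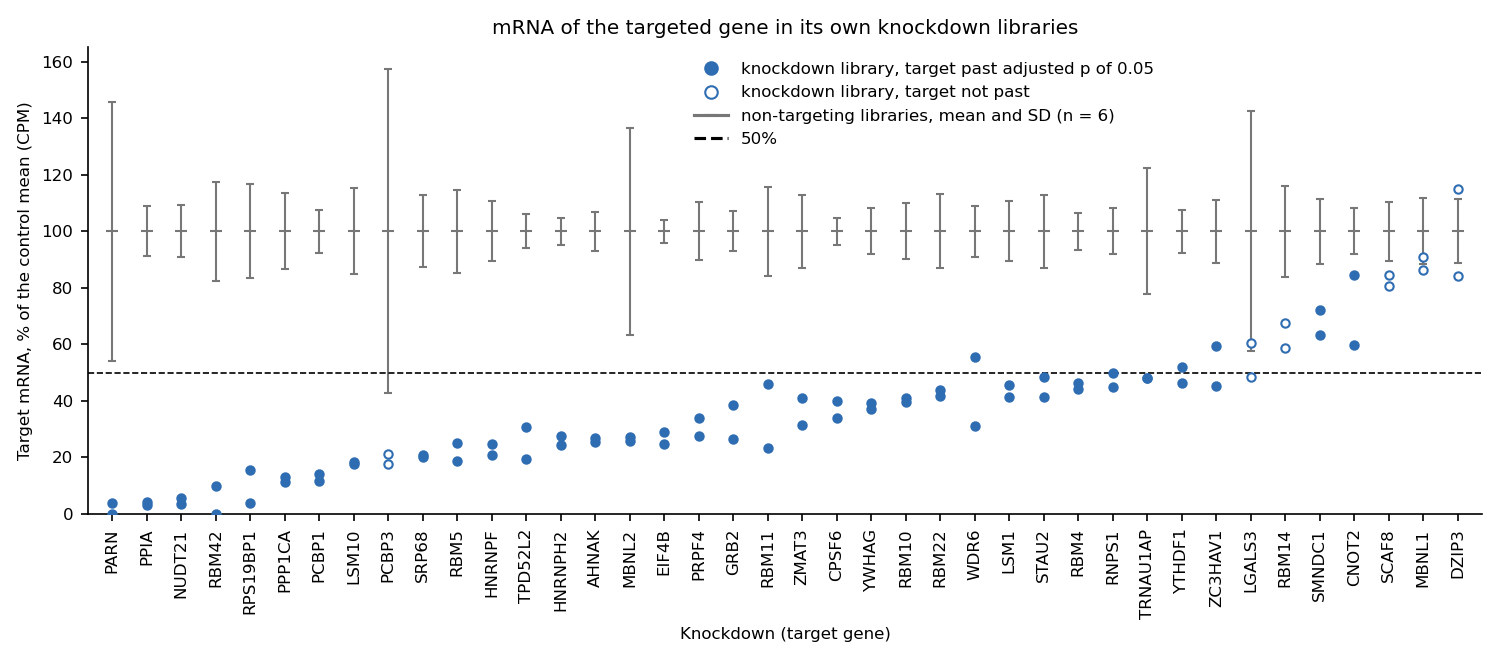
Level of each target gene in its 2 knockdown libraries, as percent of the mean of the 6 non-targeting libraries of the group, whose SD is drawn in grey; open circles are targets not past the test. The mean of 32 targets lies below the line at 50% and that of 8 above, DZIP3 (99.6%) the highest.

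The number of genes that differed from the controls ranged from 420 in PARN to 6568 in TPD52L2 knockdown. NUDT21 knockdown changed 5342 of 13914 genes and CPSF6 knockdown 2713. The 6 other knockdowns with the most calls were TPD52L2, RPS19BP1 (6261), TRNAU1AP (6231), HNRNPF (6147), MBNL2 (6030) and RBM42 (5900, or 3253 without replicate 2). The remaining 32 had a median of 3274 calls. PARN had 32 and 91 calls without replicate 1 and without replicate 2. When 2 of the 6 controls were set against the other 4, in all 15 ways per group, edgeR called 0 to 2 genes in group A and 0 to 1 in group B, with 365 to 904 and 299 to 559 genes at an unadjusted p under 0.05. Part of the change was shared by most knockdowns. TSPAN6, a tetraspanin, was higher in all 25 knockdowns of group A (median 1.20) and in all 15 of group B (median 1.14). ASPM (median 1.49, group A, but with 68.0% of its reads on unmatched transcripts), ARPC3 (1.11, group A) and COX7C (1.26, group B) were higher in every knockdown of the group named. SCD, which makes monounsaturated fatty acids, was lower in 24 of 25 knockdowns of group A (median −1.08), and RNF24 in all 15 of group B (median −0.70). In at least 60% of the knockdowns, 334 genes were higher and 430 lower in group A, and 504 and 624 in group B. These knockdowns share their controls, so the counts are not independent. Of 288 genes named by the rule 28 moved the same way in at least 60% of the group, as did 43 of the 128 fully matched genes and 162 of the 384 list members allowed by the rule. Among them DNAH17 was higher in 20 of 25 knockdowns of group A (median 2.00), while PCK1 was lower in 19 (median −1.61), INSIG1 in 21, and CRTAP and MDH2 in 22. Such genes are called common below, list members only in part. Set against the mean of the other knockdowns of the group, a reference chosen after seeing the data, CPSF6 knockdown had 2706 calls, 1248 of them among its calls against the controls with the same sign. RBM42 had 3331 (2827), the libraries labelled MBNL1 887 (435), YTHDF1 811 (187) and PARN 2313 (201).

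**Figure D2:**
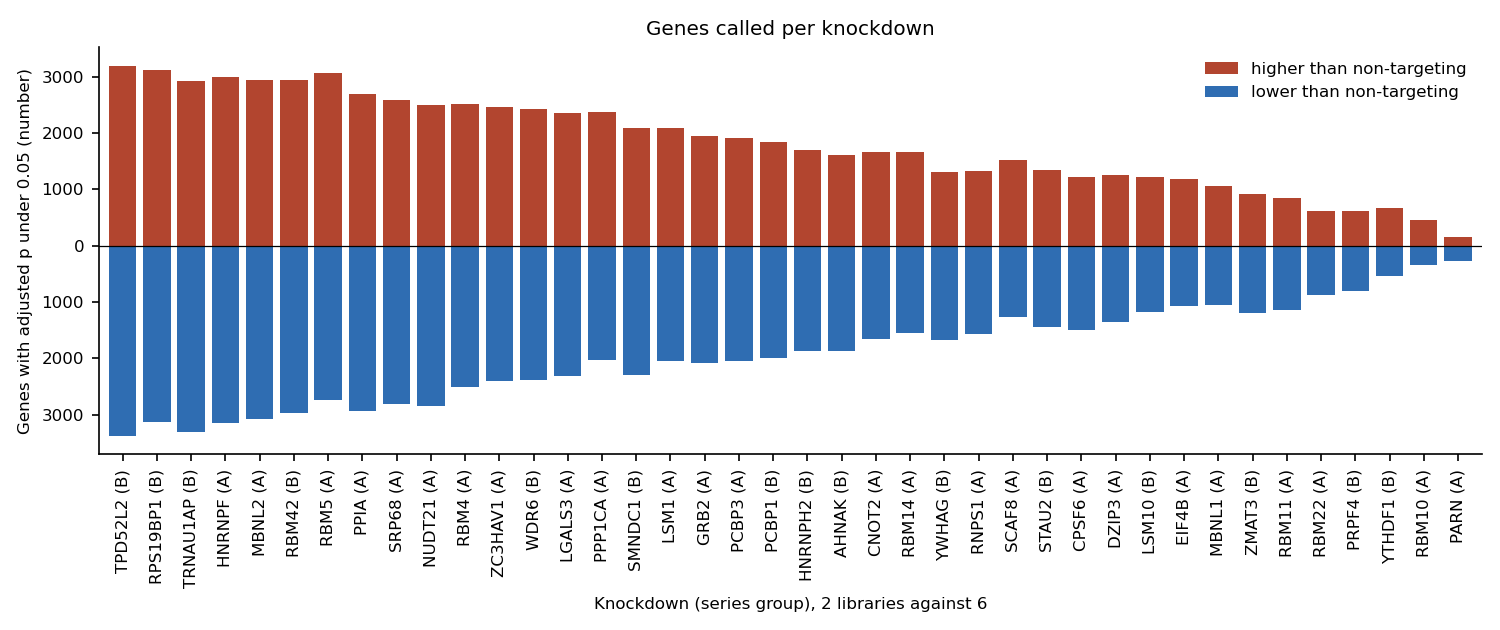
Genes called higher and lower (adjusted p under 0.05, edgeR) in each of the 40 knockdowns against the 6 controls of its group. Bars run from 420 genes in PARN to 6568 in TPD52L2 knockdown.

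In most knockdowns, genes with one particular 7-mer in the 3′ UTR lay lower than in the other knockdowns of the group, after a fit of 3′ UTR length and GC content. The scan, added after seeing the data, took the 7-mer with the lowest z in each knockdown, over 654025 tests with a Bonferroni limit of z = 5.38. It passed in 33 of 40 knockdowns (the same 7-mer in 30 of them with the shares of all bases fitted), with the lowest z for GCTTTGC in MBNL2 (−14.9), TGCTTAA in GRB2 (−13.3), GTTACCT in the libraries labelled DZIP3 (−12.5) and TTGGTCA in SCAF8 (−12.5). Among the other main comparisons, the 7-mers were CCAATTA in NUDT21 (−5.88), TGATCAC in CPSF6 (−6.34), ATGAGGA in TPD52L2 (−6.06), AAGAAGA in RPS19BP1 (−5.60, but −3.74 with all bases fitted) and GGAGGGG in RBM42 (−5.94), the last also lowest in group B as a whole (−5.36) and in no transcript of RBM42. For TRNAU1AP (ATCAGCA, −5.27) and HNRNPF (TGGCATC, −4.36) the lowest did not pass. Against the controls the same genes need not be lower: in YTHDF1 the median change was 0.0763 with TCTACTA (z = −5.74) and 0.0276 without it. The highest z passed in 5 knockdowns, at 11.2 for GGGATTA in LSM1, 7.29 in PCBP3, 6.56 in CPSF6 and 6.16 in RPS19BP1, and least in RBM14. AAGAGCA marked genes that were higher in most knockdowns, with z = 7.79 in group A and 8.51 in group B. Named genes that hold their knockdown's 7-mer or AAGAGCA are given as such below. In simulated data the scan found a planted 7-mer in 20 of 20 runs at a log2 fall of 0.2.

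**Figure D3:**
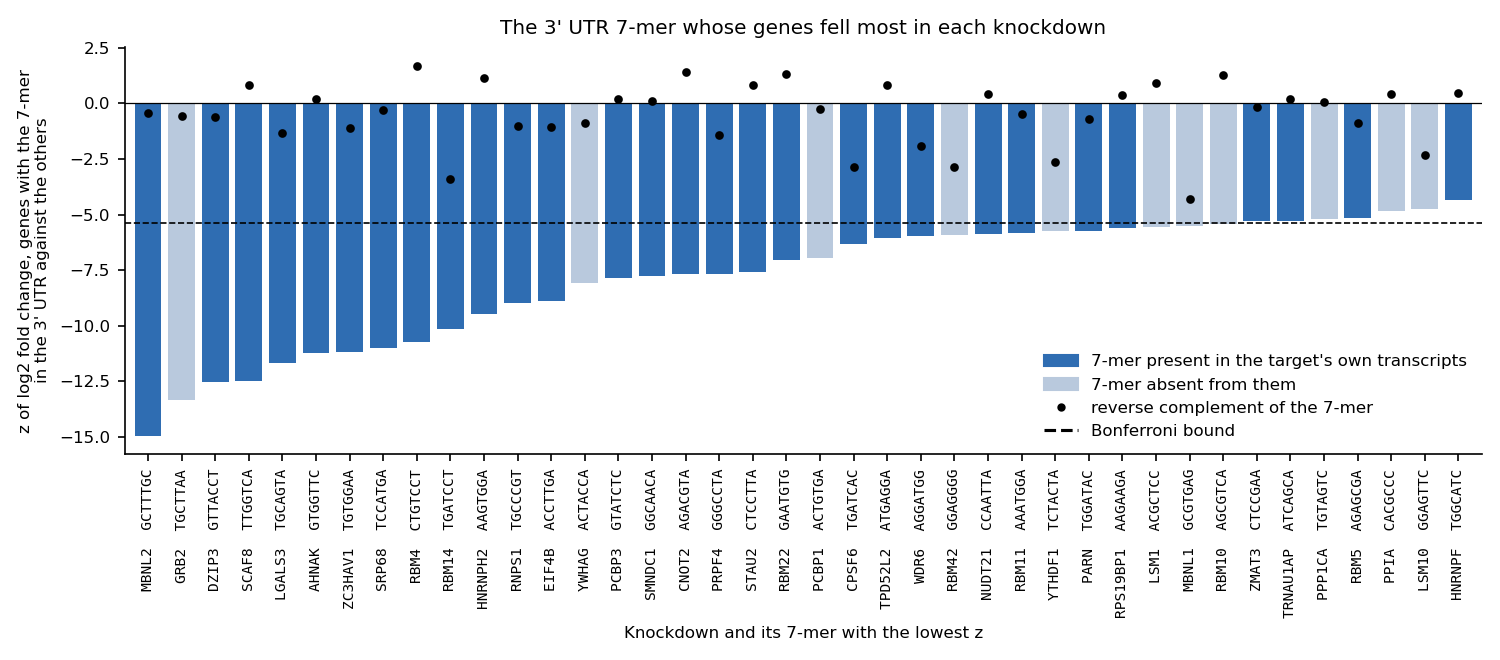
Lowest z of any 7-mer in the 3′ UTR for each knockdown, with the 7-mer written below; dark bars have it in a transcript of their own target, and dots show its reverse complement. The 33 bars beyond the Bonferroni limit of 5.38 include MBNL2 at −14.9.

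Knockdown of NUDT21 raised 2503 genes and lowered 2839. DNAH17, a heavy chain of axonemal dynein, rose from 1.26 ± 0.960 CPM to 95.5 and 158 CPM (6.59 ± 0.28, adjusted p = 3.0e-21). GLI1, a transcription factor of Hedgehog signalling (3.17 ± 0.38), KLF15 (3.07 ± 0.50), SAMD9 (3.02 ± 0.58), VPS9D1 (2.73 ± 0.45) and MYL5 (2.71 ± 0.38) rose as well. PCK1, an enzyme of gluconeogenesis, fell from 35.0 ± 6.68 to 1.55 and 1.77 CPM (−4.38 ± 0.43, adjusted p = 8.0e-11), and TAS2R5, a bitter taste receptor, fell by 3.81 ± 0.59. SYT15, which holds AAGAGCA, had 0 reads against 70 in the controls and was at least 10.8-fold lower, a call lost with offsets for length (adjusted p = 0.0790). Among fully matched genes, chosen after values were seen, the circadian repressor NR1D1 (2.65 ± 0.31), SYTL5 (2.57 ± 0.29), the mismatch repair gene MLH3 (2.47 ± 0.35), SCNN1D (2.43 ± 0.34), CUBN (2.43 ± 0.26), BRME1 (2.39 ± 0.37) and PCLO (2.33 ± 0.21) rose. FAM136A (−3.24 ± 0.15), the neuropeptide GAL (−3.18 ± 0.40), TNFRSF21 (−3.01 ± 0.22), NSA2, a factor of ribosome assembly (−2.90 ± 0.13), PAPSS2 (−2.81 ± 0.27), CRTAP (−2.63 ± 0.11) and METTL9 (−2.60 ± 0.14) fell. TNFRSF21, METTL9 and PCLO hold CCAATTA, and MLH3, PCLO, NSA2, CRTAP and METTL9 hold AAGAGCA. DNAH17, PCK1, PCLO and CRTAP are common. Of the 20 genes that the rule gave, 11 were uncertain, such as RAB33B (0 reads, at least 82.0-fold lower, with 31.3% of its reads on unmatched transcripts), and 7 of these lost their call in at least 1 setting.

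Of 79 cytosolic ribosomal protein genes, 74 fell with NUDT21 knockdown and 0 rose (74 adjusted over the list alone), with a median of −0.87 (camera adjusted p = 3.3e-42, but adjusted p = 0.0813 with an estimated correlation). RPL7A fell by 2.05 ± 0.13 and RPL6 by 1.78 ± 0.11. G2 and mitosis genes fell, 17 of 28 (19 adjusted over the list alone; adjusted p = 1.2e-07, and adjusted p = 0.213 with an estimated correlation), with CCNB1 at −1.83 ± 0.17, CDC20 at −1.59 ± 0.14 and AURKA at −1.54 ± 0.12. Cholesterol genes fell in 12 and rose in 1 of 24 (13 and 2 adjusted over the list alone; adjusted p = 1.6e-04, and adjusted p = 0.0910 with an estimated correlation), with IDI1 at −2.36 ± 0.14 and SQLE at −1.61 ± 0.12. Smaller falls, also lost with an estimated correlation, were those of hnRNP proteins (12 of 28 lower, 13 adjusted over the list alone; adjusted p = 0.0140, and adjusted p = 0.592 with an estimated correlation), such as HNRNPC (−0.74 ± 0.11), and of unfolded protein response chaperones (10 of 21, 11 adjusted over the list alone; adjusted p = 0.0267, and adjusted p = 0.452 with an estimated correlation). Spliceosome snRNP genes did likewise (16 of 38, 17 adjusted over the list alone; adjusted p = 0.0335, and adjusted p = 0.592 with an estimated correlation), with SNRPF at −0.85 ± 0.11. Of the 6 genes reported to change their 3′ end with CFIm, 5 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.0331, and adjusted p = 0.20 with an estimated correlation). CCND1 fell by 1.31 ± 0.28, PAK1 by 0.41 ± 0.11 (−0.34, adjusted p = 0.0807, without replicate 2) and DICER1 by 0.94 ± 0.30, which lost its call without either replicate (−0.86 and −1.03, adjusted p = 0.120 and 0.0603) and is uncertain. VMA21 (−1.25 ± 0.12), which holds AAGAGCA, was at 0.72 (adjusted p = 9.9e-04) with offsets for length. Counts without such offsets cannot tell fewer mRNAs of this list from shorter ones. TIMP2, whose exons overlap another gene, rose by 0.70 ± 0.15, a call lost without replicate 1 (0.39). It is common (higher in 19 and lower in 2 of 25 knockdowns of group A, median 0.64). Among 26 cleavage and polyadenylation factors 3 were higher and 5 lower (adjusted p = 0.559). The other CFIm subunits stood at −0.26 ± 0.12 (CPSF6, adjusted p = 0.0920) and −0.53 ± 0.11 (CPSF7, uncertain, which holds CCAATTA and lost its call with offsets for length, adjusted p = 0.402).

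Knockdown of CPSF6 raised 1211 genes and lowered 1502 (1491 calls with offsets for length and 1604 in a fit with only the 8 libraries). DNAH17 rose by 2.84 ± 0.35 and HFM1, a meiotic DNA helicase, by 2.77 ± 0.43. COL3A1 (2.64 ± 0.54), the complement receptor CR2 (2.38 ± 0.32) and SCNN1D (2.27 ± 0.34, or 1.35 without replicate 1) rose too. C1orf162 fell from 10.2 ± 2.99 to 1.12 and 1.24 CPM (−3.08 ± 0.47, adjusted p = 6.6e-06). The amine oxidase AOC3 (−2.08 ± 0.31) and the nicotinic receptor subunit CHRNA3 (−2.06 ± 0.31) also fell. TAS2R5 fell by 2.15 ± 0.50, and HOXB13 (−2.05 ± 0.58) lost its call with the replicate block, as TAS2R5 did (adjusted p = 0.0520), and without replicate 2 (−1.43, adjusted p = 0.150; −3.77 without replicate 1). Among fully matched genes, chosen after values were seen, were the rises PDE3B (2.02 ± 0.22, which holds AAGAGCA), GPR137C (1.76 ± 0.28), CMTM3 (1.71 ± 0.22) and H2BC5 (1.57 ± 0.24) and the falls SCD (−1.97 ± 0.10), INSIG1, a brake on sterol synthesis (−1.96 ± 0.14), YY2 (−1.86 ± 0.38) and GALNT2 (−1.82 ± 0.12). INSIG1 and GALNT2 hold TGATCAC, and GALNT2 holds AAGAGCA. DNAH17, AOC3, GPR137C, SCD and INSIG1 are common. The rule gave 20 genes here, 10 of them uncertain, such as SYNCRIP (90.1% of its reads on unmatched transcripts, holding TGATCAC), and 7 of these lost their call in at least 1 setting.

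With CPSF6 knockdown, 14 of 24 cholesterol genes fell and 0 rose (14 and 1 adjusted over the list alone), with a median of −0.70 (adjusted p = 1.8e-17, and adjusted p = 1.5e-04 with an estimated correlation); IDI1 fell by 1.47 ± 0.13 and SQLE by 1.45 ± 0.12. Of 27 replication-dependent histone genes, whose mRNAs normally lack a poly(A) tail, 10 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 1.17 (adjusted p = 2.4e-06, and adjusted p = 0.0259 with an estimated correlation); H4C14 rose by 1.38 ± 0.36, and H4C15, which holds AAGAGCA, from 44.6 ± 5.22 to 104 and 149 CPM. The next calls did not hold with an estimated correlation. Ribosomal protein genes fell in 33 of 79 (45 adjusted over the list alone; median −0.30; adjusted p = 2.9e-12, and adjusted p = 0.452 with an estimated correlation), and hypoxia and glycolysis genes in 10 of 20 (11 adjusted over the list alone; adjusted p = 7.4e-04, and adjusted p = 0.404 with an estimated correlation), with the uncertain NDRG1 at −0.96 ± 0.13. Spliceosome snRNP genes were lower in 9 of 38 (11 adjusted over the list alone; adjusted p = 0.00318, and adjusted p = 0.416 with an estimated correlation), and G2 and mitosis genes in 4 of 28 (4 adjusted over the list alone; adjusted p = 0.00987, and adjusted p = 0.603 with an estimated correlation). Unfolded protein response chaperones were higher in 7 and lower in 2 of 21 (the same adjusted over the list alone; adjusted p = 0.0137, and adjusted p = 0.403 with an estimated correlation), with HERPUD1 at 0.76 ± 0.13. CCR4-NOT and decay factors were lower in 7 of 32 (7 adjusted over the list alone; adjusted p = 0.0232, and adjusted p = 0.440 with an estimated correlation). Cleavage and polyadenylation factors were lower in 6 and higher in 2 of 26 (the same adjusted over the list alone; adjusted p = 0.0137, and adjusted p = 0.240 with an estimated correlation). These 6 include CPSF6 itself and, lost with offsets for length, NUDT21 (−0.60 ± 0.11, uncertain; 0.57, adjusted p = 0.367), WDR33 (−0.58 ± 0.09; −0.17, adjusted p = 0.637) and PAPOLA (−0.51 ± 0.09; −0.40, adjusted p = 0.0555). NUDT21 and WDR33 hold TGATCAC, and WDR33 holds AAGAGCA. CPSF7 (uncertain) stood at −0.24 ± 0.11 (adjusted p = 0.100; −0.15 without replicate 1). The CFIm list did not pass (adjusted p = 0.672, median 0.18, mean −0.01).

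The test for 3′ ends asked whether CFIm loss moved usage toward the proximal end. With NUDT21 knockdown, 129 of 1754 genes shifted to the proximal and 10 to the distal end, with a median shift of −0.60 over all genes. MAN2A2, a Golgi mannosidase on chromosome 15 with ends at 90921191 and 90922584 (hg38), shifted by −8.33 ± 1.09 (SE; adjusted p = 1.6e-06). RPL7L1, on chromosome 6 with ends at 42887301 and 42889925, shifted by −7.45 ± 0.73 (adjusted p = 7.9e-09). HNRNPA1, on chromosome 12 with ends at 54284881 and 54287087, shifted by 8.89 ± 1.33 to the distal end (adjusted p = 1.3e-05), from a log2 ratio of −10.7 ± 0.31 in the controls (SD, n = 6). TSPAN3 (−7.30 ± 1.81) lost its call without replicate 2 (−6.28, adjusted p = 0.188), and KLC1 (3.77 ± 0.88) was at 0.95 (adjusted p = 0.700) without it. Without replicate 1 the count of both directions was 83, and without replicate 2 it was 60. With CPSF6 knockdown 38 genes shifted to the proximal and 4 to the distal end, with a median of −0.31. The count was 8 and 19 without replicate 1 and without replicate 2, 23 without control replicate 5 and 25 without control replicate 6, and no single gene named by the rule kept its call in all settings. PHKA1, a subunit of phosphorylase kinase on chromosome X, stood at −4.99 ± 0.86 (adjusted p = 5.8e-04), and at −2.53 (adjusted p = 0.286) without replicate 1. In 24 genes both knockdowns shifted to the proximal end, and 0 genes shifted in opposite directions. Both share controls, which makes them alike. With 3 controls for each, an alternative added after seeing the data, 15 genes did so and 1 was opposite, or 11 and 0 with the controls exchanged, of 32 and 16 past the test with CPSF6 knockdown. Across genes the shifts correlated with r = 0.336, and 0.162 and 0.157 with their own controls. With shared controls, 46 pairs of either partner with another knockdown of group A had a median r of 0.222 and reached 0.392. With transcripts of any version, chosen after seeing the data, the counts were 460 proximal and 41 distal of 3203 genes for NUDT21 and 199 and 21 for CPSF6. When 2 controls were set against 4, limma called 0 to 7 genes in group A and 0 to 4 in group B. Of the 6 genes of the CFIm list 3 were measured. With NUDT21 knockdown TIMP2 was at −0.92 ± 0.46 (adjusted p = 0.252) and PAK1 at −1.63 ± 1.52 (adjusted p = 0.578). Neither passed the test, and their direction cannot be taken as that of the whole list.

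Among the other knockdowns HNRNPF had the most shifts, 60 proximal and 46 distal (38 without replicate 1 and 66 without replicate 2). RPL7 (12.91 ± 2.12), the annexin ANXA2 (9.51 ± 1.38) and HNRNPA1 (9.37 ± 1.33) shifted to the distal end. Their log2 ratios in the controls were −5.78, −7.91 and −10.7. RBM42 had 37 proximal and 18 distal shifts, but 33 in all without replicate 1 and 1 without replicate 2. MBNL2 had 10 proximal and 36 distal shifts (13 in all without replicate 1 and 16 without replicate 2), with RPL7L1 at 4.98 ± 0.73. RPS19BP1 had 13 and 12 (1 in all without replicate 1, and 14 and 15 without control replicates 1 and 3). TRNAU1AP had 8 and 8 (7 in all without replicate 1, and 3 to 9 without any 1 of control replicates 1 to 5), and TPD52L2 7 and 5 (0 in all without replicate 1, 1 without replicate 2, and 1 to 7 without control replicate 1, 3, 5 or 6). The genes that the rule named in the last 3 and in RBM42 all lost their call without a replicate. Of the 32 remaining knockdowns, 4 had at least 20 shifts: PPP1CA (11 proximal, 33 distal), PCBP3 (15, 27), WDR6 (24, 15) and SRP68 (13, 25). These counts are not tested against each other.

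**Figure D4:**
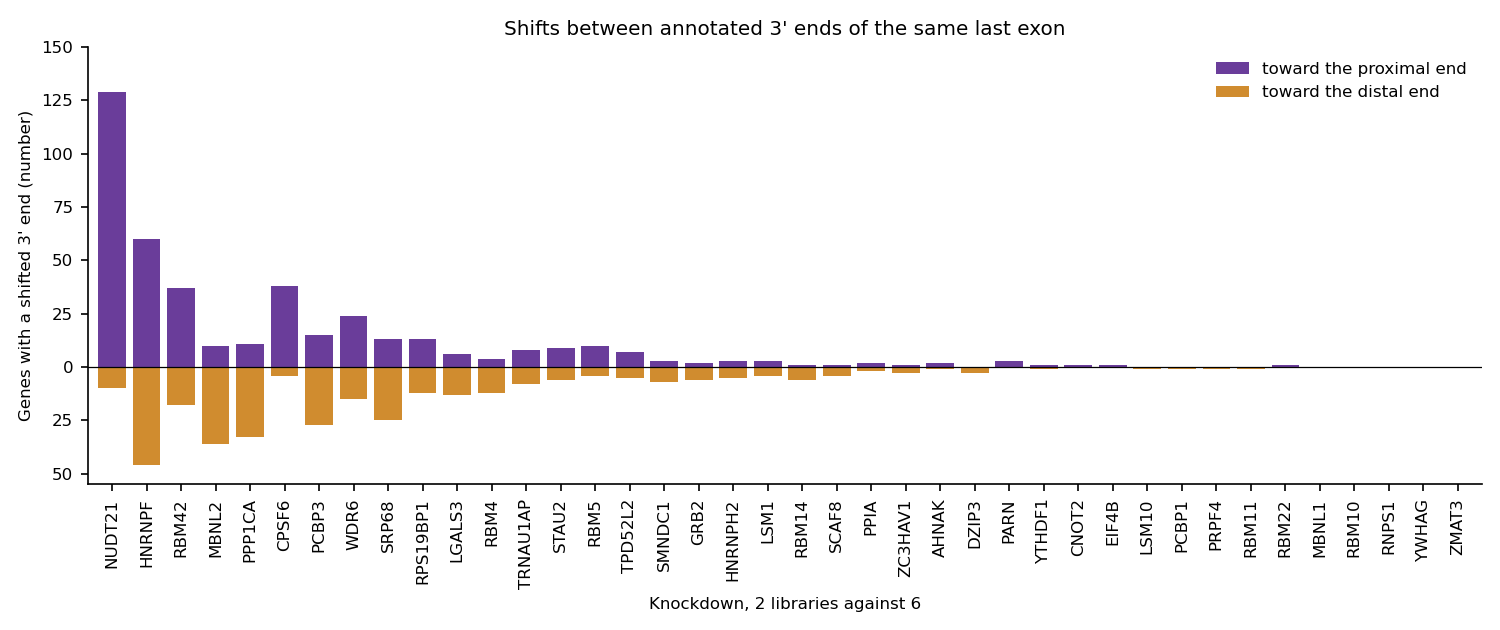
Genes shifted to the proximal and to the distal 3′ end in each knockdown (limma, adjusted p under 0.05), of 1754 genes in group A and 1753 in group B. NUDT21 stands apart with 129 proximal shifts, and CPSF6 has 38.

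A direct test of NUDT21 against CPSF6 knockdown called 3440 genes, 1515 higher and 1925 lower with NUDT21 knockdown (2077 without NUDT21 replicate 1, 2287 without CPSF6 replicate 2 and 2010 with offsets for length). CCND1 was lower by 1.83 ± 0.32 with NUDT21 knockdown (adjusted p = 3.0e-05). The histone genes H4C15 (−1.67 ± 0.23) and H2BC5 (−2.29 ± 0.32) were lower too. TIMP2, which is common, did not differ by more than its error (0.01 ± 0.19). Both knockdowns raised 530 genes and lowered 893, while 152 moved in opposite directions. Their changes correlated across genes with r = 0.363, against 0.290 in simulated data with no change and shared controls, and 0.186 when each had its own 3 controls. The covariance was 0.159 above the simulated value.

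The same comparison was made for 6 other pairs of related proteins. The libraries labelled MBNL1 and those of MBNL2 gave r = 0.437 (simulated 0.268, own controls 0.251), with 735 genes higher in both, 767 lower in both and 62 opposite. RBM4 and RBM14 gave 0.396 (simulated 0.268, own controls 0.249), with 785 shared rises, 708 shared falls and 257 opposite. LSM1 and CNOT2 gave 0.334 (simulated 0.274, own controls 0.169), with 537, 672 and 206. RBM5 and RBM10, related splicing regulators, gave 0.278 (simulated 0.273, own controls 0.105), with 286, 145 and 77. PRPF4 and SMNDC1 gave 0.272 (simulated 0.283, own controls 0.131), with 250, 274 and 118. CNOT2 and PARN, both of mRNA deadenylation, gave 0.152 (simulated 0.267) and turned to −0.01 with their own controls, with 61, 75 and 42. Shared controls alone make genes agree, so the counts have no value to be set against. The simulated data hold no effects, and unshared effects in real knockdowns can lower r below the simulated value. In this order the covariance was 0.255, 0.227, 0.149, 0.102, 0.0734 and −0.0049 above the simulated one. In genes with log2 CPM of at least 4, NUDT21 and CPSF6 gave 0.410 and the MBNL pair 0.582; pairs of either partner with any other knockdown of group A reached 0.486 and 0.646. Among paralogs, HNRNPH2, whose exons overlap another gene, rose with HNRNPF knockdown (0.98 ± 0.11), and HNRNPF (0.60 ± 0.09, uncertain) and HNRNPH3 (0.63 ± 0.13) rose with HNRNPH2 knockdown. PCBP2 fell with PCBP1 knockdown (−1.04 ± 0.10, holding AAGAGCA) and PPIF with PPIA knockdown (−1.20 ± 0.13).

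Knockdown of TPD52L2, a tumour protein D52 family member, raised 3196 genes and lowered 3372. GLB1L (3.27 ± 0.31), ANKRD1, a muscle stress protein (3.01 ± 0.23, holding AAGAGCA), TLCD1 (2.92 ± 0.41) and FILIP1L (2.55 ± 0.37) rose. NECAB2 had 0 reads against 5.03 ± 1.81 CPM in the controls, at least 13.0-fold lower, and KCNH2, a cardiac potassium channel, had 2 reads against 211, a ratio of 41.8 (11.6 to 345). Fully matched genes, chosen after values were seen, included the rises ZKSCAN8P1 (2.29 ± 0.23), ZNF107 (2.19 ± 0.16, holding AAGAGCA), SCAND3 (2.12 ± 0.25), ZNF211 (2.08 ± 0.18, holding ATGAGGA), TTC12 (2.07 ± 0.32) and TRIM66 (2.07 ± 0.18). CARMIL3 (−3.74 ± 0.47), PCK1 (−3.38 ± 0.34), ARHGEF4 (−3.30 ± 0.25), the troponin TNNT1 (−3.23 ± 0.32, holding ATGAGGA), IGFBP5 (−3.19 ± 0.36) and TSPO (−3.19 ± 0.52) fell, as did the connexin GJA3 (−3.29 ± 0.45, holding AAGAGCA; −5.45 without replicate 1). ANKRD1, KCNH2, ZNF107, ARHGEF4, TNNT1, IGFBP5, TSPO and SRSF3 are common. Of 24 p53 targets 17 rose and 0 fell (17 and 1 adjusted over the list alone), with a median of 0.52 (adjusted p = 9.0e-06, and adjusted p = 0.00275 with an estimated correlation). CDKN1A rose by 1.95 ± 0.14 and SESN1 by 1.46 ± 0.15. Ribosomal protein genes fell in 71 of 79 (73 adjusted over the list alone; adjusted p = 5.8e-22, and adjusted p = 0.370 with an estimated correlation). Cholesterol genes fell in 17 of 24 (17 adjusted over the list alone; adjusted p = 7.5e-08, and adjusted p = 0.152 with an estimated correlation), with SQLE at −1.72 ± 0.12. SR proteins rose in 9 of 14 (9 adjusted over the list alone; adjusted p = 0.00749, and adjusted p = 0.566 with an estimated correlation), with SRSF3 at 0.77 ± 0.08. Mitochondrially encoded genes rose in 6 and fell in 1 of 13 (7 and 1 adjusted over the list alone; adjusted p = 0.0398, and adjusted p = 0.744 with an estimated correlation). Of the 20 genes of the rule 12 were uncertain, and 10 of these lost their call in at least 1 setting, as did RGPD5.

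Knockdown of RPS19BP1, a partner of ribosomal protein S19, raised 3125 genes and lowered 3136. CGA, the common subunit of glycoprotein hormones, rose from 6.32 ± 3.36 to 57.5 and 67.6 CPM (3.36 ± 0.30, adjusted p = 8.1e-10). The nuclear receptor NR4A2 (2.92 ± 0.25), CCN2 (2.78 ± 0.34), the metallothionein MT1X (2.73 ± 0.33) and RBKS (2.31 ± 0.37) rose, and so did SIK1 (2.78 ± 0.50; 2.13, adjusted p = 0.229, with offsets for length). LRRC39 had 0 reads against 64 in the controls, at least 4.75-fold lower. Fully matched genes, chosen after values were seen, included the rises OR2AT4 (2.11 ± 0.29), H2BC21 (2.06 ± 0.26), CCNL1 (2.04 ± 0.21), ANKRD60 (1.88 ± 0.29), NR4A1 (1.87 ± 0.16) and NPAP1 (1.87 ± 0.32). The falls were ASIC3 (−3.65 ± 0.45), PCYOX1L (−3.26 ± 0.56, with 0 reads in replicate 1), MST1 (−3.12 ± 0.33), the DNA crosslink nuclease DCLRE1A (−2.87 ± 0.27), ARNT2 (−2.87 ± 0.37), PIP4K2A (−2.73 ± 0.21), the intermediate filament NES (−2.69 ± 0.38) and NEURL1B (−2.68 ± 0.30). CCNL1, NR4A1 and PCYOX1L hold AAGAAGA, and NPAP1 and NEURL1B hold AAGAGCA. OR2AT4, CCNL1, MST1, ARNT2, NES and NEURL1B are common. No list kept its call with an estimated correlation here. G2 and mitosis genes rose in 21 of 28 (24 adjusted over the list alone; adjusted p = 5.6e-09, and adjusted p = 0.248 with an estimated correlation), with PTTG1 at 1.52 ± 0.11. Rises were also called for hnRNP proteins (22 of 28; adjusted p = 4.2e-07, and adjusted p = 0.20 with an estimated correlation), such as HNRNPH3 (1.38 ± 0.12), snRNP proteins (24 of 38; adjusted p = 4.2e-05, and adjusted p = 0.412 with an estimated correlation) and immediate early genes (10 of 18; adjusted p = 3.6e-04, and adjusted p = 0.143 with an estimated correlation), such as ATF3 (1.11 ± 0.16). Adjusted over the list alone these counts were the same. Of 79 ribosomal protein genes 38 rose and 8 fell (41 and 8 adjusted over the list alone; adjusted p = 0.00546, and adjusted p = 0.850 with an estimated correlation), with RPL23A at −1.68 ± 0.12. Heat shock genes (9 of 15), SR proteins (8 of 14), mitochondrially encoded genes (9 of 13), decay factors (16 of 32) and cleavage factors (15 of 26) had more rises than falls (9, 9, 9, 18 and 15 rises adjusted over the list alone), with adjusted p from 0.00726 to 0.0364 (adjusted p from 0.371 to 0.651 with an estimated correlation). S phase genes fell in 12 of 25 (12 adjusted over the list alone; adjusted p = 0.0331, and adjusted p = 0.566 with an estimated correlation), with MCM3 at −0.91 ± 0.10. Of the 20 genes of the rule 13 were uncertain, and 9 of these lost their call in at least 1 setting.

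Knockdown of TRNAU1AP, which acts with the tRNA for selenocysteine, raised 2929 genes and lowered 3302. TP53I3, a p53 target, rose from 0.951 ± 0.753 to 53.7 and 36.9 CPM (5.45 ± 0.57, adjusted p = 5.4e-09). DNAH17 (3.40 ± 0.32), ZNF658 (3.36 ± 0.36), DOLK, the dolichol kinase (3.12 ± 0.47), NAP1L2 (2.96 ± 0.38) and CFAP43 (2.92 ± 0.40) rose. PCK1 fell from 34.3 ± 4.06 to 1.08 and 0.964 CPM (2.99% of the controls, adjusted p = 2.4e-10) and DEPP1 by 3.58 ± 0.46. HES7 had 2 reads against 152 in the controls, a ratio of 25.2 (6.97 to 208), and RGCC 2 against 77, a ratio of 14.2 (3.95 to 118). The fully matched genes, chosen after values were seen, included the rises of the cytokine LIF (2.77 ± 0.34), TTC12 (2.67 ± 0.32), PSKH1 (2.66 ± 0.31), APBB3 (2.60 ± 0.18), PLEKHG4 (2.58 ± 0.37), ZNF594 (2.55 ± 0.23) and PRMT6 (2.55 ± 0.34). GPRC5A (−3.22 ± 0.22), INSIG1 (−2.99 ± 0.15), the scaffold protein AHNAK (−2.91 ± 0.12), MYOM2 (−2.82 ± 0.48) and RGS16 (−2.79 ± 0.35) fell, and CGA fell by 2.97 ± 0.60 (−1.89 without replicate 1, which has 0 reads). DEPP1 and GPRC5A hold ATCAGCA, and AHNAK is common. Of 24 p53 targets 19 rose and 2 fell (20 and 2 adjusted over the list alone), with a median of 1.12 (adjusted p = 1.5e-09, and adjusted p = 1.5e-04 with an estimated correlation). FDXR rose by 2.20 ± 0.17, XPC by 1.92 ± 0.14 and MDM2 by 1.54 ± 0.09 (uncertain, holding AAGAGCA), while PMAIP1, which promotes apoptosis, fell by 1.84 ± 0.13 (under 0.1% of its reads unmatched). Cholesterol genes fell in 16 and rose in 2 of 24 (the same adjusted over the list alone), with a median of −1.60 (adjusted p = 5.1e-13, and adjusted p = 0.0415 with an estimated correlation); IDI1 fell by 2.88 ± 0.16 and SQLE by 2.36 ± 0.13. Ribosomal protein genes fell in 71 of 79 (72 adjusted over the list alone; adjusted p = 7.4e-18, and adjusted p = 0.429 with an estimated correlation). Hypoxia and glycolysis genes fell in 16 of 19 (16 adjusted over the list alone; adjusted p = 7.8e-08, and adjusted p = 0.120 with an estimated correlation), with P4HA1 at −2.44 ± 0.13 and LDHA at −1.18 ± 0.13. Falls also prevailed among G2 and mitosis (22 of 28), immediate early (9 of 18), ATF4 (13 of 31) and nonsense-mediated decay genes (10 of 17), and rises among mitochondrially encoded genes (9 of 13), with adjusted p from 8.0e-05 to 0.0376 (adjusted p from 0.130 to 0.541 with an estimated correlation) and the same counts adjusted over the list alone. The selenoprotein list did not pass in any knockdown (smallest adjusted p = 0.0801). Of the 20 genes of the rule 10 were uncertain, and 5 of these lost their call in at least 1 setting.

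Knockdown of HNRNPF, a splicing regulator that binds G-runs, raised 2991 genes and lowered 3156. CMYA5, a muscle protein, rose from 2.54 ± 0.808 to 111 and 107 CPM (5.38 ± 0.29, adjusted p = 5.6e-18). The histone gene H4C14 (4.28 ± 0.30), ANKRD1 (4.27 ± 0.26, holding AAGAGCA), DNAH17 (3.80 ± 0.33) and SAMD9 (3.46 ± 0.59) rose. DLEC1 had 0 reads against 45 in the controls, at least 3.85-fold lower. With full matching, and chosen after values were seen, the rises were ALDH8A1 (2.88 ± 0.34), ZNF530 (2.76 ± 0.24) and DRP2 (2.61 ± 0.28). TSPAN18 (−3.13 ± 0.38), the mitochondrial malate dehydrogenase MDH2 (−3.01 ± 0.17), CTDSP1 (−2.93 ± 0.48), GRIP2 (−2.87 ± 0.38), the ferritin light chain FTL (−2.83 ± 0.18), LRRC20 (−2.82 ± 0.31), the cadherin CDH23 (−2.81 ± 0.40) and RHBDL3 (−3.09 ± 0.46; −4.84 without replicate 1) fell. TSPAN18, RHBDL3, LRRC20 and CDH23 hold TGGCATC, and GRIP2 holds AAGAGCA. DNAH17, ZNF530, MDH2, GRIP2 and FTL are common. Cholesterol genes fell in 19 of 24 and 0 rose (20 and 0 adjusted over the list alone), with a median of −0.82 (adjusted p = 5.1e-10, and adjusted p = 0.00434 with an estimated correlation). SREBF2, a transcription factor of the pathway, fell by 1.83 ± 0.13, and SQLE by 1.19 ± 0.12. Histone genes rose in 13 of 27 and 0 fell (the same adjusted over the list alone), with a median of 1.23 (adjusted p = 2.5e-05, and adjusted p = 0.0473 with an estimated correlation), with H2AC11 at 3.12 ± 0.32. Ribosomal protein genes fell in 67 of 79 (69 adjusted over the list alone; adjusted p = 2.2e-23, and adjusted p = 0.228 with an estimated correlation), with RPL8 at −2.24 ± 0.19. S phase genes fell in 12 of 25 (13 adjusted over the list alone; adjusted p = 0.00148, and adjusted p = 0.342 with an estimated correlation). Chaperones of the unfolded protein response rose in 8 and fell in 5 of 21 (9 and 5 adjusted over the list alone; adjusted p = 0.00383, and adjusted p = 0.325 with an estimated correlation), with HERPUD1 at 2.56 ± 0.12. G2 and mitosis genes rose in 15 and fell in 6 of 28 (16 and 7 adjusted over the list alone; adjusted p = 0.0151, and adjusted p = 0.629 with an estimated correlation), with CENPF at 1.43 ± 0.13 and the uncertain AURKB at −1.09 ± 0.15. Among the 20 genes of the rule 14 were uncertain, and 9 of these lost their call in at least 1 setting.

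Knockdown of MBNL2, a muscleblind splicing regulator, raised 2947 genes and lowered 3083. DNAH17 rose from 1.26 ± 0.960 to 66.7 and 52.8 CPM (5.51 ± 0.29, adjusted p = 3.5e-18). SAMD9 (4.55 ± 0.54), TTC30A (4.18 ± 0.42), the collagens COL24A1 (4.09 ± 0.32) and COL3A1 (3.68 ± 0.50), DNAH6 (3.42 ± 0.36) and H4C14 (3.37 ± 0.31) rose. PDK3, which holds AAGAGCA, had 0 reads against 147 in the controls, at least 17.9-fold lower, and PCK1 fell by 4.59 ± 0.45. Fully matched genes, chosen after values were seen, included the rises ZNF658 (2.92 ± 0.33), CLGN (2.74 ± 0.18) and TRAK2 (2.61 ± 0.21). CYSTM1 (−3.36 ± 0.24), the amino acid transporter SLC7A3 (−3.33 ± 0.43), JPH3 (−3.22 ± 0.40), WNK4 (−3.13 ± 0.55), the small GTPase RAC1 (−2.91 ± 0.13), GRIP2 (to 12.3% of the controls) and LAPTM4B (12.6%) fell. PCK1, CYSTM1, JPH3, GRIP2, LAPTM4B and RAC1 hold GCTTTGC, as does the rise H4C14, and GRIP2 holds AAGAGCA. DNAH17, TTC30A, PCK1, CLGN, GRIP2, RAC1, P4HA1 and INSIG1 are common. No list kept its call with an estimated correlation. Ribosomal protein genes fell in 69 of 79 (74 adjusted over the list alone; adjusted p = 2.0e-14, and adjusted p = 0.403 with an estimated correlation). Hypoxia and glycolysis genes fell in 14 of 20 (14 adjusted over the list alone), with a median of −1.06, or −0.93 with a member without reads at its bound (adjusted p = 9.6e-08, and adjusted p = 0.151 with an estimated correlation); ENO1 fell by 2.07 ± 0.12 and holds GCTTTGC, and P4HA1 by 1.77 ± 0.15. G2 and mitosis genes fell in 17 and rose in 3 of 28 (the same adjusted over the list alone; adjusted p = 2.2e-04, and adjusted p = 0.421 with an estimated correlation), with BIRC5 at −1.91 ± 0.10 and CENPF at 1.28 ± 0.13. Falls also prevailed among S phase (18 of 25), snRNP (21 of 38), cholesterol (11 of 24) and nonsense-mediated decay genes (6 of 17), with adjusted p from 3.3e-04 to 0.0442 (adjusted p from 0.215 to 0.371 with an estimated correlation); MCM3 fell by 1.07 ± 0.10 and INSIG1 by 2.41 ± 0.14. Adjusted over the list alone, the snRNP count was 22 and the others were the same. Among the 20 genes of the rule 9 were uncertain, and 6 of these lost their call in at least 1 setting, as did HIST2H2AA3 and SYT15, which holds AAGAGCA.

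Knockdown of RBM42, an RNA-binding protein, raised 2931 genes and lowered 2969. Of the 20 genes of the rule 19 were uncertain and 15 of these lost their call in at least 1 setting; ANKRD1 alone was not, rising from 4.15 ± 0.674 to 17.0 and 19.8 CPM (2.13 ± 0.25, adjusted p = 9.4e-08, holding AAGAGCA). Fully matched genes, chosen after values were seen, included the rises XAF1 (from 7.57 ± 2.46 to 25.4 and 28.8 CPM), the coagulation factor F5 (1.79 ± 0.30), TAF1D (1.75 ± 0.21), OR10G4 (1.75 ± 0.30), GLIPR1L2 (1.75 ± 0.24) and MT-ND6 (1.71 ± 0.34). STMN3, which destabilises microtubules (−3.28 ± 0.35), GDPD5 (−3.10 ± 0.37), the adhesion protein NECTIN1 (−3.09 ± 0.30), RAB39A (−2.95 ± 0.32), CLIP2 (−2.93 ± 0.42), RELL2 (−2.85 ± 0.46), PALM (−2.83 ± 0.45) and PRXL2B (−2.78 ± 0.44) fell. STMN3, NECTIN1, CLIP2, PALM and PRXL2B hold GGAGGGG. ANKRD1, XAF1, GLIPR1L2, STMN3, GDPD5, NECTIN1, CLIP2, PALM, PHGDH, TRA2A and TRA2B are common. ATF4 targets fell in 15 and rose in 1 of 31 (17 and 1 adjusted over the list alone), with a median of −0.48 (adjusted p = 1.2e-07, and adjusted p = 0.0133 with an estimated correlation). PHGDH (−1.88 ± 0.12), PSAT1 (−1.51 ± 0.12) and SLC7A11 (−1.90 ± 0.21, holding AAGAGCA) were among them. SR proteins rose in 12 and fell in 1 of 14 (13 and 1 adjusted over the list alone; adjusted p = 5.9e-06, and adjusted p = 0.257 with an estimated correlation), with TRA2A at 1.35 ± 0.16 and TRA2B at 1.01 ± 0.12. Ribosomal protein genes fell in 41 and rose in 4 of 79 (44 and 6 adjusted over the list alone; adjusted p = 6.2e-06, and adjusted p = 0.734 with an estimated correlation). G2 and mitosis genes rose in 15 of 28 (15 adjusted over the list alone; adjusted p = 5.2e-04, and adjusted p = 0.566 with an estimated correlation), with CENPE at 1.05 ± 0.11. Heat shock genes rose in 8 and fell in 2 of 15 (8 and 4 adjusted over the list alone; adjusted p = 0.00807, and adjusted p = 0.371 with an estimated correlation), with a median of 0.49 and a mean of −0.21. hnRNP proteins rose in 13 and fell in 4 of 28 (the same adjusted over the list alone; adjusted p = 0.0402, and adjusted p = 0.641 with an estimated correlation).

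In the other 32 knockdowns the rule names 2 rises and 2 falls each, of which those without unmatched or overlapping transcripts that kept their call in every setting are given. DNAH17 rose in LGALS3 (5.01 ± 0.30), AHNAK (3.58 ± 0.31), RBM11 (3.44 ± 0.33) and SCAF8 knockdown (3.14 ± 0.34), and SAMD9 in ZC3HAV1 (4.34 ± 0.55) and LGALS3 knockdown (4.01 ± 0.56, there holding the 7-mer). H4C14 rose in PPIA (4.77 ± 0.30), COL3A1 in ZC3HAV1 (4.24 ± 0.48), ANKRD1 in YWHAG (3.56 ± 0.22, holding AAGAGCA), the beta globin HBB in WDR6 (3.54 ± 0.58), IGFN1 in STAU2 (3.35 ± 0.41) and CFAP43 in SCAF8 knockdown (3.16 ± 0.38). In HNRNPH2 knockdown TNC (3.13 ± 0.43) and ALDH8A1 (2.83 ± 0.35) rose. With knockdown of ZMAT3, itself a p53 target, CGA rose by 4.14 ± 0.29 and PCK1 by 2.73 ± 0.19, and INPP5D fell (3 reads against 133 in the controls, a ratio of 17.2, 5.90 to 83.6). TTC30A rose in the libraries labelled MBNL1 (2.67 ± 0.46), in RNPS1 (2.58 ± 0.46) and in RBM22 knockdown (2.27 ± 0.47). COX5A fell from 123 ± 14.4 to 13.9 and 10.5 CPM (−3.34 ± 0.18, adjusted p = 7.1e-17) in the libraries labelled DZIP3 and holds their 7-mer GTTACCT. CARMIL3 fell there by 4.39 ± 0.63 (0 reads in replicate 1). DNAH17 and TTC30A in group A, ANKRD1 in group B and CARMIL3 are common.

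Across the 895 list tests 290 passed, 41 of them also with an estimated correlation. Cholesterol genes were lower in 33 and higher in 2 of 40 knockdowns, and 22 of the falls hold with an estimated correlation. With shared controls these are not independent, and IDI1 and SQLE are themselves common in group A (lower in 22 and 20 of 25). The smallest adjusted p was that of RBM11 knockdown (20 of 24 lower, 21 adjusted over the list alone; median −1.18; adjusted p = 8.8e-08 with an estimated correlation), with MSMO1 at −2.50 ± 0.20 and IDI1 at −2.16 ± 0.14. In RBM4 knockdown 21 of 24 fell, and in AHNAK knockdown 20 (21 and 22 adjusted over the list alone). Of p53 targets 12 rose and 3 fell with PPIA knockdown (the same adjusted over the list alone; adjusted p = 0.00102 with an estimated correlation), with TP53INP1 at 2.29 ± 0.13; with RBM11 knockdown 9 rose and 3 fell (13 and 3 adjusted over the list alone; adjusted p = 0.0283 with an estimated correlation), among the falls CDKN1A (−1.46 ± 0.21). In RBM10 knockdown the p53 list was lower (adjusted p = 0.0171 with an estimated correlation) with 0 of 24 members past the edgeR test and 3 adjusted over the list alone. Histone genes rose with SRP68 (18 of 27), RBM4 (16 of 27) and PPIA knockdown (11 of 27) and fell with AHNAK knockdown (9 of 23), all with an estimated correlation (adjusted p from 0.0171 to 0.0473; 20, 17, 11 and 9 adjusted over the list alone); H2BC5 rose by 2.72 ± 0.22 with RBM4 and H1-2 fell by 2.35 ± 0.27 with AHNAK knockdown. S phase genes fell with PPIA (22 of 25, also adjusted over the list alone; adjusted p = 0.00748 with an estimated correlation) and SRP68 knockdown (19 of 25, or 20 adjusted over the list alone; adjusted p = 0.0231 with an estimated correlation), MCM4 by 1.57 ± 0.09 with PPIA. G2 and mitosis genes rose with PCBP1 knockdown in 26 of 28 (26 adjusted over the list alone; adjusted p = 0.0171 with an estimated correlation), KIF20A by 1.46 ± 0.13. Heat shock genes rose with RBM5 knockdown in 10 of 15 (11 adjusted over the list alone; adjusted p = 0.0353 with an estimated correlation), HSPA8 by 1.41 ± 0.13. ATF4 targets fell with PARN (6 of 31), STAU2 (11 of 31) and in the libraries labelled MBNL1 (10 of 31; 8, 13 and 10 adjusted over the list alone), with adjusted p from 0.0211 to 0.0473 with an estimated correlation.

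With the preset correlation alone, p53 targets were higher in 6 and lower in 1 of 40 knockdowns, histone genes higher in 7 and lower in 4, S phase genes lower in 21 and higher in 1, and G2 and mitosis genes higher in 16 and lower in 7. Heat shock genes were higher in 7 and lower in 5, and ATF4 targets lower in 16 and higher in 3. No call of the lists that follow held with an estimated correlation. Ribosomal protein genes were lower in 28 and higher in 4 of 40 knockdowns, SR proteins higher in 23, snRNP genes lower in 17 and higher in 1, and hypoxia genes lower in 14 and higher in 5. hnRNP proteins were higher in 10 and lower in 3, mitochondrially encoded genes higher in 7 and lower in 10, immediate early genes higher in 3 and lower in 8, and chaperones of the unfolded protein response higher in 8 and lower in 2. Decay factors were higher in 4 and lower in 2, nonsense-mediated decay genes lower in 5, and cleavage factors higher in 2 and lower in 1. Interferon-stimulated genes were higher with YWHAG (adjusted p = 0.00873, and adjusted p = 0.152 with an estimated correlation) and LGALS3 knockdown (adjusted p = 0.0331, and adjusted p = 0.0996 with an estimated correlation). The CFIm list was lower with NUDT21 knockdown and higher in the libraries labelled DZIP3 (adjusted p = 0.00987, and adjusted p = 0.133 with an estimated correlation). Markers of fibroblasts (smallest adjusted p = 0.163) and of haematopoietic cells (0.452, tested in the 15 knockdowns of group B) passed in no knockdown by camera. Of the 290 calls, 3 had a mean against the test: G2 and mitosis genes with SCAF8 (−0.01) and WDR6 knockdown (−0.02), and the heat shock list with RBM42 knockdown; 0 had such a median, under each scaling tried as well.

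**Figure D5:**
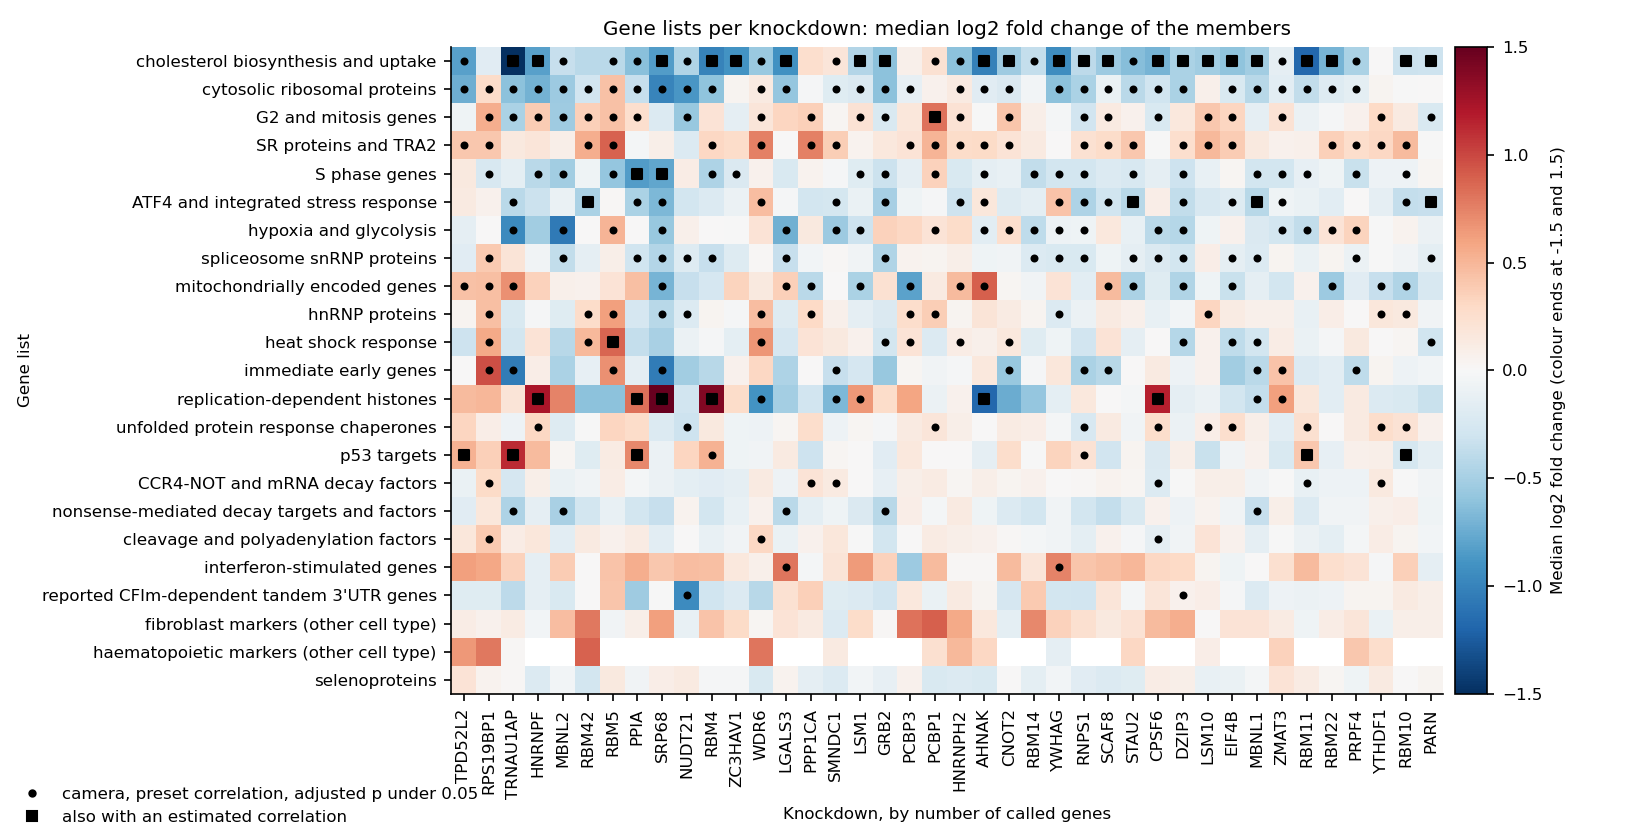
Median log2 change of each of the 23 gene lists in each knockdown, by colour, with marks for tests past an adjusted p of 0.05 at the preset and with an estimated correlation. At the preset, cholesterol genes are lower in 33 knockdowns and SR proteins higher in 23, of which 22 and 0 hold with an estimated correlation.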

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

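The tests chosen only after the result was seen are those of the shares of all bases, of AAGAGCA in group B, of the GC trend as the only cause, and of the genes at 0 reads; the scan itself was added after counts of called genes were seen.

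In 33 of 40 knockdowns, genes with one 7-mer in the 3′ UTR lay lower than in the other knockdowns of the group, as far as z = −14.9 for GCTTTGC in MBNL2. If the hairpin itself acted on these genes through its seed, which pairs with the target as well, the 7-mer would occur in the target's transcripts: it did in 25 of the 33, against a mean of 10.8 and at most 21 in 10000 reassignments of 7-mers to knockdowns. Base composition of the 3′ UTR is argued against for most of them, since with the shares of all bases fitted 30 of the 33 stayed past the limit of 5.38. It stays open for the other 3, where z went from −5.60 to −3.74 (RPS19BP1), from −5.74 to −4.68 (YTHDF1) and from −5.42 to −5.30 (RBM10). Rises go beyond this: the highest z passed in 5 knockdowns, at 11.2 for GGGATTA in LSM1, where the lowest was −5.56, so z of this size can have a source other than the knockdown hairpin's seed, which stays open. Off-target silencing by the hairpin may be part of many changes in the report; hairpin sequences are not given, and a biological effect, of the loss of the target or another shared by genes with the same 7-mer, stays open and untested.

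TSPAN6 and SCD stand for the 764 genes of group A and 1128 of group B that differed from the controls in most knockdowns. A candidate source is the seed of the non-targeting hairpin, whose own targets would look higher in every knockdown: AAGAGCA, found in group A, had z = 8.51 in group B and ranked 1 there. The genes' own AAGAGCA is argued against as the whole cause. Of the common higher genes of group B 32.57% hold it, against 19.5% of the others. Other sites and indirect effects of the hairpin were not tested, so the hairpin as the whole cause stays open. A GC trend between libraries as the only cause is argued against by the numbers after the GC correction, 773 genes in group A and 739 in group B. Of these, 460 and 453 were so before it. As part of the cause it cannot be told apart from others, because 48.26% of the genes in all were still called so, 60.2% in group A but 40.2% in group B. A response to any hairpin that acts, biological or not, was not tested and stays open, since each group has 1 kind of control.

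In 110 genes, RAB33B and PDK3 among them, both libraries of a knockdown had 0 reads. Missing transcripts are a candidate explanation: 61.82% of these genes had over 10% of their reads on unmatched transcripts, against 8.86% of genes called lower but never at 0 (Fisher's exact p = 2.3e-42). Of the 40 without unmatched transcripts 75% overlap the exons of another gene, against 10.2% (Fisher's exact p = 8.8e-22), so that reads assigned to one or the other may account for them. For 10 genes neither holds and the fall stays open, and no biological explanation was tested.

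Control replicate 3 of group A stood far from the other 5 in 4 of 50 tests of single values, where chance gives about 1 in 20. Its 10 most abundant genes took 11.56% of the reads (7.36% to 8.84% in the others). It had NUDT21 at 106.1 CPM (127 to 139), PCBP3 at 7.877 CPM (2.28 to 3.72) and RBM11 at 17.15 CPM (25.6 to 27.8). Without it the targets NUDT21, PCBP3 and RBM11 kept their side of the threshold.

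Reads outside the comparisons were higher than in all controls in some libraries. Spike-in and phiX reads were highest in NUDT21 replicate 2 at 0.372% (controls 0.21% to 0.315%, 4 of 50 libraries above) in group A. In group B they were highest in ZMAT3 replicate 2 at 0.434% (controls 0.022% to 0.356%, 6 of 30 above). Reads on unmatched transcripts were highest in RBM5 replicate 2 at 8.57% (controls 7.15% to 7.78%, 30 of 50 above) in group A, and in RBM42 replicate 2 at 8.456% (controls 7.30% to 7.71%, 24 of 30 above) in group B.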

How the results depend on the processing

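Tests chosen only after seeing the data are the GC correction, shares of all bases in the 7-mer scan, own controls for 3′ shifts, the mean of the other knockdowns as reference, and transcripts whose version differs. Unless a reason is given, the cause of a change was not tested.

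With RLE factors, with DESeq2 and without a filter on low counts, all 40 counts of called genes stayed within 1.5 times the main count, and so they did without any 1 control. The labels do not say that a replicate number marks a shared culture or day. The difference between replicates 1 and 2 of a knockdown, correlated across genes with that of control replicates 1 and 2, was above 0.1 in 5 of 40 knockdowns (median 0.0298, from −0.141 to 0.171), so the number was not taken as a pairing. Only controls have numbers above 2, so with the block each of those takes its own term. Control replicates 1 and 2 alone are then the reference, for lists and 3′ shifts too. With this smaller reference the block gave lower counts in 20 knockdowns: CNOT2 1832, CPSF6 1594, DZIP3-labelled 1447, EIF4B 972, LSM1 2460, MBNL1-labelled 1168, PARN 184, PCBP3 2365, PPP1CA 2270, RBM10 315, RBM11 1143, RBM14 1948, RBM22 836, RNPS1 1546, SCAF8 1477, LSM10 1287, PCBP1 2431, PRPF4 725, YTHDF1 326, ZMAT3 1345. Offsets for transcript length gave lower counts in 16: CPSF6 1491, DZIP3-labelled 1533, EIF4B 1210, LSM1 2704, MBNL1-labelled 1124, PARN 82, PCBP3 2423, RBM10 279, RBM11 937, RBM22 595, RNPS1 1600, SRP68 3589, PRPF4 582, YTHDF1 495, YWHAG 1686, ZMAT3 846. Against CPSF6, NUDT21 knockdown had 2010 calls with these offsets. Against the mean of the other knockdowns, another question than against the controls, the counts were CNOT2 2098, DZIP3-labelled 1301, GRB2 2447, MBNL1-labelled 887, PARN 2313, RBM10 1757, RBM4 3275, RNPS1 1133, AHNAK 1973, LSM10 1252, PCBP1 2143, PRPF4 2265, RBM42 3331, SMNDC1 2280, STAU2 1147, WDR6 2791, ZMAT3 3422. The GC correction gave PARN 633, PPP1CA 1993, SMNDC1 2654, and a fit with only the 8 libraries of the comparison gave CPSF6 1604. The correction kept call and sign in 3284 of 5900 RBM42, 4450 of 6147 HNRNPF and 6096 of 6231 TRNAU1AP calls. Changes correlated with gene GC content at rho from −0.662 (PPP1CA) to 0.247 (NUDT21). Leaving out 1 knockdown library leaves fewer samples. Over all libraries left out in turn, the counts that either knockdown library moved over 1.5-fold were DZIP3-labelled 1080 to 2542, EIF4B 752 to 2230, GRB2 2177 to 3993, LGALS3 2867 to 4577, MBNL1-labelled 532 to 2115, PARN 32 to 409, PCBP3 2143 to 3933, PPIA 3680 to 5543, PPP1CA 1925 to 4329, RBM10 236 to 780, RBM11 647 to 2042, RBM22 501 to 1480, RBM4 3074 to 4945, RNPS1 1046 to 2820, SCAF8 1256 to 2763, AHNAK 1605 to 3359, HNRNPH2 1926 to 3500, LSM10 439 to 2417, PCBP1 1876 to 3829, PRPF4 398 to 1503, SMNDC1 2340 to 4265, YTHDF1 229 to 1205, YWHAG 1248 to 2978, ZMAT3 791 to 2030. Without replicate 1 alone so did SRP68 3446 to 5280, and without replicate 2 alone CNOT2 1103 to 3222, LSM1 2551 to 4044, RBM14 1099 to 3787, ZC3HAV1 2957 to 4772, RBM42 3253 to 5865, STAU2 470 to 2823, WDR6 1819 to 4883. NUDT21 against CPSF6 ranged from 2077 (without NUDT21 replicate 1; 2287 without CPSF6 replicate 2) to 3540, and the counts of the remaining knockdowns stayed within 1.5 times.

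Of the 40 targets, 37 kept their direction and side of the threshold with offsets for length, and the others stood at CNOT2 −0.40, ZC3HAV1 −0.05, SMNDC1 −0.22, no longer past it. Past it came MBNL1-labelled −0.36, SCAF8 −0.42 with the GC correction, PCBP3 −2.27, RBM14 −0.65 with only the 8 libraries, and RBM14 −0.64 with DESeq2. With libraries left out, CNOT2 ranged from −0.74 to −0.24, PARN from −8.98 (over a library with 0 reads, so no measure of size) to −4.66 and RBM11 from −2.10 to −1.12, each losing its call in at least 1 case; the other 37 kept theirs. Of 810 genes named or allowed by the rule, the following no longer passed: 1 with RLE factors, 18 without a filter, 23 with the GC correction, 26 (of 804 tested) with only the 8 libraries, 29 with DESeq2, 66 with offsets for length, 119 with the block, 154 without knockdown replicate 1 and 145 without replicate 2, and 16 to 22 without 1 control. Offsets for length also turned 6 to the other sign: VMA21 (0.72) with NUDT21, NUDT21 (0.57), SSR1 (0.22) and CNOT6 (0.04) with CPSF6, and MDGA1 with PARN (−0.30) and RBM11 knockdown (−0.15). Of these only VMA21 passed the test.

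Of the 290 list calls, 247 passed with the block, and 41 with an estimated correlation, which widens the error of lists whose members move together. No scaling moved the median of all genes by more than 0.051. With own controls for each partner, pair correlations were 0.19 (NUDT21 and CPSF6), 0.25 (MBNL1-labelled and MBNL2), 0.10 (RBM5 and RBM10), 0.25 (RBM4 and RBM14), 0.17 (LSM1 and CNOT2), 0.13 (PRPF4 and SMNDC1) and, reversed, −0.01 (CNOT2 and PARN); sharing controls raises a correlation by construction. At log2 CPM of at least 4 the MBNL pair gave 0.58. The 3′ shifts of NUDT21 and CPSF6 gave 0.16 with own controls, an alternative added after seeing the data. In the 7-mer scan 30 of 33 stayed past the limit with the shares of all bases fitted.

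Counts of 3′ shifts depended most on the settings. Ends over 500 nt apart left all 8 within 1.5 times. The block gave CPSF6 20, TPD52L2 0, RPS19BP1 7, TRNAU1AP 2, HNRNPF 42, MBNL2 15, RBM42 18, and a pseudocount of 0.1 TPM gave CPSF6 25, RPS19BP1 10, TRNAU1AP 10, RBM42 30. Without the filter on TPM more genes were tested, with NUDT21 443, CPSF6 91, TPD52L2 118, RPS19BP1 186, TRNAU1AP 170, HNRNPF 328, MBNL2 228, RBM42 204. Transcripts of any version also add genes: NUDT21 501, CPSF6 220, TPD52L2 71, RPS19BP1 151, TRNAU1AP 52, HNRNPF 405, MBNL2 159, RBM42 200. Against the other knockdowns the counts were NUDT21 269, TPD52L2 0, RPS19BP1 15, TRNAU1AP 35, RBM42 8. With 1 library left out they ranged from 60 to 145 (NUDT21), 8 to 40 (CPSF6), 0 to 16 (TPD52L2), 1 to 37 (RPS19BP1), 3 to 14 (TRNAU1AP), 38 to 114 (HNRNPF), 13 to 50 (MBNL2), 1 to 57 (RBM42). The number of other knockdowns with at least 20 shifts, 4, was 18 without the filter, 0 with the block and 15 with any version. With any version TSPAN3 in NUDT21 knockdown turned to 1.33 and passed the test, and SSR2 in CPSF6 (−0.59) and MELK in MBNL2 knockdown (0.66) turned without passing. The 3′ test had little reach here: with 2 knockdown libraries it recovered 2% of planted shifts of 1 log2 unit.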

Other observations

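Some gene groups moved in knockdowns outside the main comparisons with the preset correlation. With knockdown of RBM5, all 14 SR proteins rose (14 adjusted over the list alone; median 0.89; adjusted p = 3.0e-12, and adjusted p = 0.0637 with an estimated correlation), and CHORDC1 (1.55 ± 0.12) and the cochaperone FKBP4 (1.16 ± 0.08) rose among the heat shock genes. With PPP1CA knockdown 13 of 14 SR proteins rose (13 adjusted over the list alone; adjusted p = 2.9e-12, and adjusted p = 0.0637 with an estimated correlation). With AHNAK knockdown 12 of 13 mitochondrially encoded genes rose (13 adjusted over the list alone; median 0.90; adjusted p = 2.3e-15, and adjusted p = 0.0913 with an estimated correlation). Among ATF4 targets, PHGDH (−0.70 ± 0.11) and the secreted hormone STC2 (−0.72 ± 0.14) fell with knockdown of STAU2, which binds double-stranded RNA. Interferon-stimulated genes rose in 8 of 26 with LGALS3 and in 3 of 24 with YWHAG knockdown, the same adjusted over the list alone. Neither list passed with an estimated correlation.

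The labels spell 3 targets in more than one way: AKNAK beside AHNAK, HNRNH2 for HNRNPH2, and NUDT21 with its other name CPSF5. In the libraries labelled AKNAK, AHNAK was at 69.1 and 65.3 CPM against 256 ± 17.5 (SD, n = 6) in the controls.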
